A study of Homo sapiens with 18 samples.

How the data were processed

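RNA abundance was measured by RNA-seq in 18 libraries of the human pancreatic ductal adenocarcinoma lines PANC1 and CFPAC1. Per the labels, PANC1 was transfected with a plasmid that carries a Cas9 nickase and puromycin resistance, and 3 bulk lines labelled FOXA2-deleted stood beside 3 wild-type bulk lines. CFPAC1 was transfected with control siRNA, FOXA1 siRNA, FOXA2 siRNA or both siRNAs, with 3 libraries each. Libraries were made by SMART-Seq2 from 10 ng of polyA RNA with Tn5 tagmentation and were unstranded, so reads of overlapping or antisense genes could not be told apart. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, aligned to GRCh38 with TopHat2 2.1.0, counted per gene with featureCounts (no version given) and tested with edgeR 3.2.2.

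The authors deposited whole-number counts of reads per gene, not normalized, for 27123 features in 18 libraries. The authors also deposited 4 tables of log2 fold changes with their p-values and false discovery rates, made with edgeR. These tables were used only where the text names the authors' deposited table. Of the 27123 features, 27060 matched a GENCODE 29 gene by identifier, 25988 of them with the same version, and 19618 were protein-coding. All 27123 features named a gene, so none was left out of the library totals. Library totals ranged from 20614259 to 28023340 counts. Intervals cover counting error and the spread between libraries as edgeR models them, and reads without molecular identifiers are not independent molecules.

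Counts were analysed in R 4.3.3 with edgeR 4.0.16, one fit for PANC1 (6 libraries), one for CFPAC1 (12 libraries, 4 groups) and a joint fit of 12 libraries (both PANC1 groups, and CFPAC1 with control and FOXA2 siRNA) for comparisons across lines. Low genes were removed with filterByExpr, library sizes were scaled by TMM, and groups were compared with the robust quasi-likelihood F-test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 changes used edgeR's default prior count, and CPM values used TMM-scaled library sizes. A prior count of 2 entered only the log2 CPM of the library checks and of the GC offset described below. SE was the absolute log2 change divided by the square root of the F statistic. The 95% intervals of folds used that SE with normal quantiles. The biological coefficient of variation was 0.283 in PANC1, 0.0787 in CFPAC1 and 0.211 in the joint fit. The comparisons were FOXA2-deleted against wild-type PANC1, each CFPAC1 knockdown against control and against each other, the non-additivity of the double knockdown, the difference between the changes with the FOXA2-deleted label in PANC1 and the FOXA2 siRNA label in CFPAC1, and the control libraries of both lines. Non-additivity was the double knockdown change minus the sum of both single changes.

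Gene lists were tested against the other genes with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation. The lists were epithelial identity, mesenchymal and EMT, foregut and pancreas transcription factors, classical and basal-like subtype, mucins, liver secretory genes, acute phase and complement, interferon response, inflammatory cytokines and NF-kB targets, cell cycle, p53 targets, unfolded protein and integrated stress response, cholesterol biosynthesis, YAP/TEAD targets, RAS/MAPK output, hypoxia and glycolysis, WNT targets, acinar, endocrine, fibroblast, endothelial, leukocyte, neural and mitochondrially encoded genes. List sizes ranged from 8 to 46 genes.

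Groups, comparisons, thresholds, gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. Named genes were FOXA1, FOXA2 and FOXA3, LINC00261 and genes within 1 Mb of FOXA2, and the 10 largest rises and 10 largest falls of each comparison of a deletion or knockdown with its control. Other comparisons allowed 5 of each. These genes had to be protein-coding, called, at a mean of at least 5 CPM in the higher group, and without overlap between both groups of 3 libraries. Up to 4 members with the smallest adjusted p could be named from each gene list, and the text names fewer than the rule allows.

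That first set held DESeq2 size factors, no filter on low counts, the replicate number as a block, a fold minimum of 1.5 (glmTreat), the DESeq2 1.42.0 Wald test, other libraries in the fit, each library left out in turn, the estimated correlation, and a threshold of 0.01 for overlaps of calls. Alternatives added after the data were seen were an offset for transcript GC content, that offset with the block, the likelihood-ratio test, limma-voom with and without library quality weights, and PANC1 without wild-type library 1 and FOXA2-deleted library 3. The replicate numbers were checked for pairing: libraries with the same number were the best match across groups in 1 of 6 PANC1 and 5 of 12 CFPAC1 libraries, so the numbers were not used to pair samples. Within each group no library was a copy of another, with a chi-square per gene between 3.80 and 166.

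The tests were checked on simulated libraries with known changes. Their counts were drawn from a negative binomial model with each gene's mean and dispersion in the real counts. Trends between the real libraries were not in that model, apart from a GC trend where named, so these figures may not hold for the real libraries. With 3 simulated PANC1 libraries in each group, a 2-fold change was recovered in 17.9% and a 4-fold change in 83.3% of genes, with 9 false among 77 calls. The likelihood-ratio test made 38 false calls among 131 there. In CFPAC1, a 2-fold change was recovered in 83.6% of genes for both the FOXA2 and the double knockdown, with 10 false among 176 and 172 calls. A simulated GC trend gave 1586 false calls without and 8 with the GC offset. Shared control libraries make changes correlate, so overlaps of calls were set beside 20 simulations and beside changes from separate libraries. Sequence variants at the FOXA2 locus, isoforms, chromatin binding and protein were not analysed here. Figures were drawn with matplotlib 3.10.9.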

Results

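RNA abundance was compared in 18 libraries of the established pancreatic ductal adenocarcinoma lines PANC1 and CFPAC1, which the study sets apart by their grade of differentiation. PANC1 was represented by 3 wild-type bulk lines and 3 bulk lines labelled FOXA2-deleted. CFPAC1 was represented by 3 libraries each of control siRNA, FOXA1 siRNA, FOXA2 siRNA and both siRNAs. Total counts were 28023340, 22147694 and 25657061 in the wild-type PANC1 libraries and 24162083, 22855744 and 24879696 in the FOXA2-deleted ones. In CFPAC1 they were 20887030, 21360365 and 22792066 with control siRNA, 22062046, 21015494 and 21905281 with FOXA1 siRNA, 20614259, 21726539 and 20952690 with FOXA2 siRNA, and 20725383, 21454049 and 22656142 with both. Between 16577 and 17602 genes had counts in a library. The labels do not say whether the 3 CFPAC1 libraries of a group came from separate transfections, so p-values may measure technical spread.

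FOXA1 and FOXA2 encode forkhead factors that open chromatin in foregut-derived epithelia. FOXA2 (ENSG00000125798.14, GRCh38 chromosome 20, 22581005 to 22585455, minus strand) had 60, 48 and 59 counts in the wild-type PANC1 libraries and 153, 207 and 166 in those labelled FOXA2-deleted. These were 2.20 ± 0.0646 and 7.38 ± 1.46 CPM (SD, n = 3), a log2 difference of 1.75 (SE 0.25; adjusted p = 0.0854, edgeR). A deleted gene can still give a transcript, so this value does not check the deletion or the labels. An exchange of the PANC1 labels was not excluded and would turn the direction of every PANC1 result. In CFPAC1, FOXA2 had 21, 13 and 7 counts with control siRNA, 11, 15 and 20 with FOXA1 siRNA, 27, 31 and 13 with FOXA2 siRNA, and 23, 38 and 31 with both. FOXA2 was not lower in the libraries labelled FOXA2 siRNA, where the fold against control was 1.70 with a 95% interval of 0.978 to 2.97 (adjusted p = 0.267). With both siRNAs FOXA2 rose from 0.657 ± 0.358 to 1.38 ± 0.339 CPM (log2 1.08, SE 0.40, n = 3; fold 2.12, 95% interval 1.24 to 3.63; adjusted p = 0.0345). That FOXA2 call was lost without control library 2 (adjusted p = 0.0883), control library 3 (0.182), double-knockdown library 2 (0.142) or double-knockdown library 3 (0.0646), with DESeq2 (0.0642) and with the GC offset (0.0591). The lower bound of 0.978 with FOXA2 siRNA rested on 7 to 21 counts with control siRNA, so a small fall of FOXA2 mRNA is not excluded.

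FOXA1 (ENSG00000129514.5, chromosome 14, 37589984 to 37595034, minus strand) had 79, 32 and 54 counts with control siRNA in CFPAC1, 36, 41 and 77 with FOXA1 siRNA, 78, 83 and 53 with FOXA2 siRNA, and 58, 29 and 43 with both. The fold of FOXA1 against control was 0.915 (95% interval 0.578 to 1.45; adjusted p = 0.891) with FOXA1 siRNA and 0.751 (0.47 to 1.2; adjusted p = 0.387) with both. The sign of the FOXA1 difference with FOXA1 siRNA changed without control library 1 (log2 0.26) or FOXA1 siRNA library 1 (0.08). Against control, a decrease of FOXA1 was not detectable over the spread between these libraries. With both siRNAs against FOXA2 siRNA alone, the fold of FOXA1 was 0.584 (95% interval 0.370 to 0.923). That decrease had an unadjusted p of 0.0339 but was not called (adjusted p = 0.149, edgeR). All groups are therefore named by their labels. FOXA1 had 4, 2 and 3 counts in the wild-type PANC1 libraries and 0 in each FOXA2-deleted library, too few for a fold. FOXA3 stayed below 1 CPM on average in every CFPAC1 group. The long noncoding RNA LINC00261, which lies next to FOXA2, averaged 32.9 ± 11.8 CPM in wild-type and 28.3 ± 8.13 CPM in FOXA2-deleted PANC1 (n = 3; adjusted p = 0.921).

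**Figure D1:**
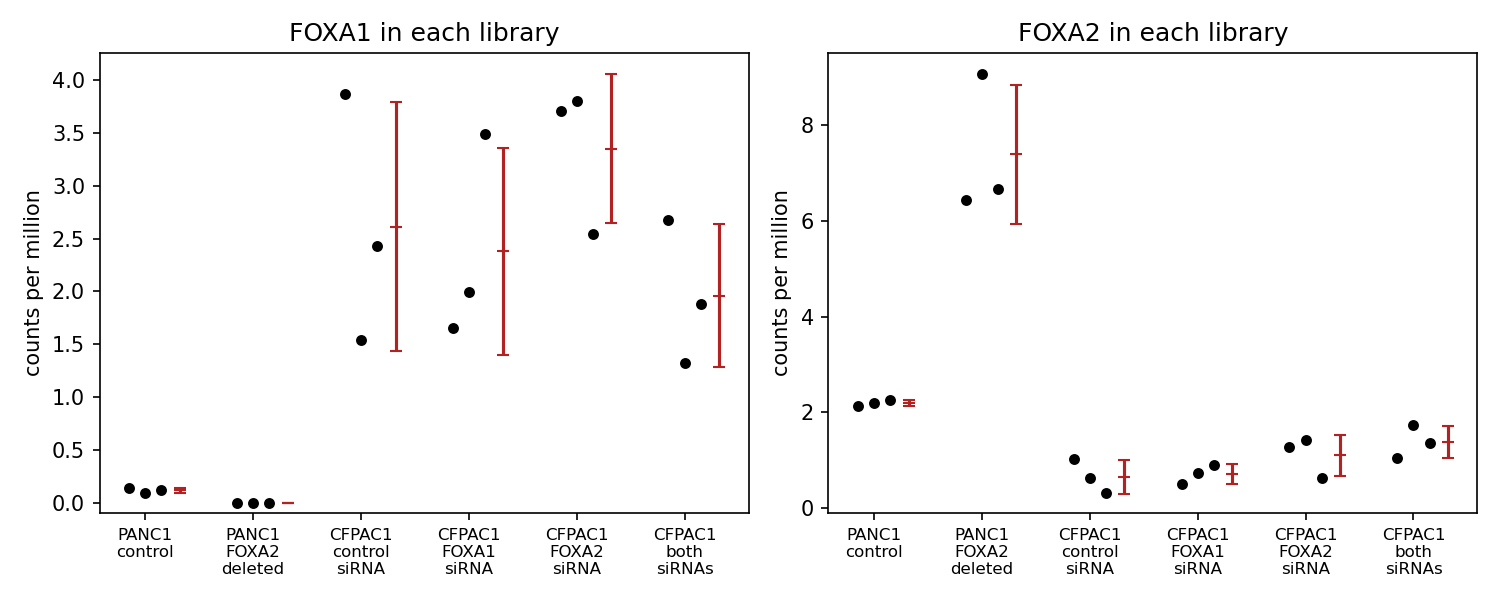
Abundance of FOXA1 and FOXA2 (CPM, vertical axis) in each library (black dots) of the 6 groups (horizontal axis), with the mean and SD in red. FOXA2 in PANC1 lies higher in the 3 libraries labelled FOXA2-deleted, and neither gene lies clearly lower in the CFPAC1 libraries labelled with its siRNA.

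The PANC1 libraries labelled FOXA2-deleted were compared to the wild-type ones. RHBDL2, which encodes a membrane rhomboid protease, fell from 27.5 ± 3.63 to 6.04 ± 0.537 CPM (SD, n = 3; log2 -2.19, SE 0.20). RBP4, the plasma carrier of retinol, fell from 10.3 ± 3.42 to 1.34 ± 0.298 CPM (log2 -2.93, SE 0.33). CLU, which encodes the chaperone clusterin, fell by 1.80 on the log2 scale (SE 0.18), and HEG1 and PLEKHH2 fell by 2.05 (SE 0.23) and 2.28 (SE 0.23). RSPO2, a secreted enhancer of WNT signalling, rose from 0 to 2 counts per wild-type library to between 74 and 137 counts. RSPO2 lay outside the rule for naming genes and was chosen after its values were seen. In total edgeR called 8 of 12666 genes, 1 higher and 7 lower, with a median absolute log2 change of 2.53. An unadjusted p under 0.05 was reached by 1019 genes, and 1839 genes did not overlap between the groups, where chance gives 10%. The calls fell to 1 without wild-type library 1 and to 0 without any single one of the other 5 libraries (656 to 1296 genes at an unadjusted p under 0.05). Without each library in turn, the adjusted p of CLU was 0.0696 to 0.321. Wild-type library 1 lay at -45.0 on the first principal component (47.0% of the variance) and had 6.64% mitochondrial counts, compared to 3.52 to 4.60% in the other PANC1 libraries.

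Inflammatory genes were higher as a list in the FOXA2-deleted PANC1 libraries, although edgeR called 0 members. CXCL2 differed by 3.66 (SE 1.21, n = 3) and CXCL8 by 1.97 (SE 0.67) on the log2 scale, both neutrophil chemokines, with 19 of 20 members positive (camera adjusted p = 1.42e-08, or 0.347 with an estimated correlation). In that list 9 members had an unadjusted p under 0.05, and DESeq2 called 2, the likelihood-ratio test 1 and limma with quality weights 0. The interferon response list was also higher, with 32 of 41 members positive (adjusted p = 4.98e-07, or 0.347 with an estimated correlation), where HERC5 differed by 2.42 (SE 0.38) and the RNA sensor DDX58 by 0.79 (SE 0.13). THY1 (log2 1.06, SE 0.16) and COL6A1 (log2 1.56, SE 0.34) were the leading members of the mesenchymal and EMT list, which was higher with 22 of 31 positive (adjusted p = 0.000105, or 0.178 with an estimated correlation). The classical subtype list was lower (5 tested, adjusted p = 0.000854, or 0.347 with an estimated correlation), with TFF3 at -3.16 (SE 0.80) and AGR2 at -2.21 (SE 0.71). edgeR called 0 members of the interferon, EMT and classical lists, where 10, 9 and 3 had an unadjusted p under 0.05 and DESeq2 called 4, 3 and 1. Adjusted over the list alone, 0 inflammatory, 3 interferon and 4 EMT genes were higher and 2 classical genes lower. With the preset correlation these 4 calls held without each library in turn.

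The calls of 6 other lists in PANC1 depended on single libraries. The cell cycle list was higher (adjusted p = 0.000105, or 0.604 with an estimated correlation) but changed direction without wild-type library 1 (0.516). The mitochondrially encoded list was lower (adjusted p = 0.00501, or 0.604 with an estimated correlation), and its call ended without wild-type library 1 (0.516) or FOXA2-deleted library 3 (0.181). The liver secretory list was lower with RBP4 as its only called member, and 1 higher and 2 lower of 8 adjusted over the list alone (adjusted p = 0.00719, or 0.347 with an estimated correlation), a call that ended without wild-type library 1 (0.167), without FOXA2-deleted library 3 (0.0613) and with the GC offset (0.0862). The basal-like list was higher (adjusted p = 0.00835, or 0.347 with an estimated correlation), except without FOXA2-deleted library 3 (0.194). The RAS/MAPK list was higher (adjusted p = 0.00337, or 0.44 with an estimated correlation), except without wild-type library 2 (0.0543) or FOXA2-deleted library 3 (0.168). The acute phase list was lower (adjusted p = 0.00493, or 0.347 with an estimated correlation), except without wild-type library 1 (0.236) or 3 (0.201) or FOXA2-deleted library 1 (0.0751) or 2 (0.146). Without both wild-type library 1 and FOXA2-deleted library 3, these 6 lists were not called (adjusted p = 0.0719 to 0.536). The fibroblast list was not called in PANC1 (4 tested, adjusted p = 0.53), where its median was -0.23 while the test pointed up.

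The CFPAC1 libraries labelled FOXA1 siRNA were compared to those with control siRNA. TFF1, a trefoil factor secreted with mucus, fell from 79.6 ± 9.43 to 43.8 ± 2.08 CPM (SD, n = 3; log2 -0.86, SE 0.08; adjusted p = 9.78e-07). S100P fell by 0.59 (SE 0.08), the mucin glycosyltransferase GCNT3 by 0.51 (SE 0.07) and the secretory-lineage factor SPDEF by 0.39 (SE 0.06) on the log2 scale. THBD, which encodes the anticoagulant receptor thrombomodulin and lies within 1 Mb of FOXA2, rose from 17.5 ± 0.752 to 25.8 ± 2.29 CPM (log2 0.56, SE 0.10; adjusted p = 0.00528). The classical subtype list was lower with 4 of 15 members called, TFF1, AGR2 (log2 -0.36, SE 0.05), CEACAM6 (log2 -0.33, SE 0.05) and ST6GALNAC1 (log2 -0.35, SE 0.07), and 6 lower adjusted over the list alone (camera adjusted p = 5.62e-10, or 0.0726 with an estimated correlation). The ST6GALNAC1 call ended without FOXA1 siRNA library 1 (adjusted p = 0.0784). CEACAM6 has close paralogs, so its reads may be split between them. Cholesterol biosynthesis was lower with 3 of 22 members called, IDI1 first (log2 -0.32, SE 0.06), and 5 lower adjusted over the list alone (adjusted p = 7.77e-06, or 0.475 with an estimated correlation). In total 23 genes rose and 62 fell of 13539 tested, with a median absolute log2 change of 0.364. The excess of falls was absent without control library 3 (26 and 26) and without the filter on low counts (227 and 195), and small with the likelihood-ratio test (85 and 91). Without control library 2, control library 3, FOXA1 siRNA library 1 or FOXA1 siRNA library 3 the 85 calls became 39, 52, 45 and 35.

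The CFPAC1 libraries labelled FOXA2 siRNA were also compared to control. CST1, which encodes the secreted cysteine protease inhibitor cystatin SN, fell from 55.4 ± 2.84 to 20.9 ± 3.52 CPM (SD, n = 3; log2 -1.41, SE 0.10; adjusted p = 3.35e-10). TFF1 fell by 1.28 (SE 0.09), the tight junction gene CLDN1 by 1.25 (SE 0.08), the IL-33 receptor gene IL1RL1 by 1.52 (SE 0.11) and the thrombin inhibitor gene SERPIND1 by 1.75 (SE 0.25) on the log2 scale. DHRS2, a mitochondrial reductase gene, rose by 1.61 (SE 0.19), COL8A1 by 1.37 (SE 0.13) and the collagenase gene MMP13 by 0.98 (SE 0.16). CST1 lies in a cluster with CST2 and CST4, so its reads may be split between paralogs. In total 546 genes rose and 731 fell of 13539 tested, with a median absolute log2 change of 0.345, and 3593 genes did not overlap between the groups, where chance gives 10%.

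Among the lists, inflammatory genes were lower with FOXA2 siRNA, with 12 of 25 called lower and 0 higher, also adjusted over the list alone (camera adjusted p = 6.02e-12, or 0.0577 with an estimated correlation). The cytokine gene IL6 fell from 62.1 ± 3.19 to 31.2 ± 2.25 CPM (n = 3), CSF2 fell by 1.09 (SE 0.13) and TNFAIP3 by 0.84 (SE 0.12) on the log2 scale. The hypoxia and glycolysis list was lower, with 9 called lower and 1 higher of 26 and 12 lower adjusted over the list alone (adjusted p = 3.31e-06, or 0.236 with an estimated correlation), led by ANGPTL4 (log2 -1.02, SE 0.10). Classical subtype genes were lower, with 6 called lower and 1 higher of 15, also adjusted over the list alone (adjusted p = 9.11e-08, or 0.0577 with an estimated correlation), among them ANXA10 (log2 -0.65, SE 0.05). The cell cycle list was higher, with 15 called higher and 1 lower of 38 and 17 higher adjusted over the list alone (adjusted p = 9.11e-08, or 0.1 with an estimated correlation), and CCNB2 rose by 0.48 (SE 0.05) while PLK1 fell by 0.48 (SE 0.05). Cholesterol biosynthesis was higher with 9 of 22 called, 11 adjusted over the list alone, in contrast to FOXA1 siRNA (adjusted p = 0.000722, or 0.253 with an estimated correlation). The basal-like list was lower with 6 called lower and 2 higher of 23 (7 and 3 adjusted over the list alone; adjusted p = 0.0006, or 0.0577 with an estimated correlation), including DHRS9 (log2 -0.75, SE 0.06). Epithelial identity genes were lower with 7 called lower and 1 higher of 42 (8 and 1 adjusted over the list alone; adjusted p = 0.00177, or 0.253 with an estimated correlation). Mucins were higher with MUC1 as the called member of 9, 3 adjusted over the list alone (adjusted p = 0.00477, or 0.253 with an estimated correlation), but the MUC1 call was lost with the GC offset (adjusted p = 0.108).

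The remaining called lists with FOXA2 siRNA rested on single libraries. The interferon list was higher (7 higher and 2 lower of 46, 9 and 2 adjusted over the list alone; adjusted p = 0.0238, or 0.253 with an estimated correlation), except without control library 1 (0.0615) or FOXA2 siRNA library 2 (0.114). YAP/TEAD targets were called lower (5 lower and 1 higher of 22, 5 and 3 adjusted over the list alone; adjusted p = 0.0129, or 0.253 with an estimated correlation), with a mean of -0.08 and a median of 0.02. The YAP/TEAD call ended without control library 1 (0.0548) and with the GC offset (0.194). RAS/MAPK output was lower (adjusted p = 0.026, or 0.242 with an estimated correlation), except without FOXA2 siRNA library 2 (0.114) and with the GC offset (0.0669). The stress response list was lower (adjusted p = 0.038, or 0.253 with an estimated correlation), except without control library 2 (0.0704), control library 3 (0.0886) or FOXA2 siRNA library 2 (0.105). Mitochondrially encoded genes, of which edgeR called 0 of 13 (3 at an unadjusted p under 0.05, 0 by DESeq2), were called as a list (adjusted p = 0.0296, or 0.502 with an estimated correlation), except without control library 2 (0.0704), control library 3 (0.109), FOXA2 siRNA library 2 (0.861) or 3 (0.0977) and with the GC offset (0.0669).

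**Figure D2:**
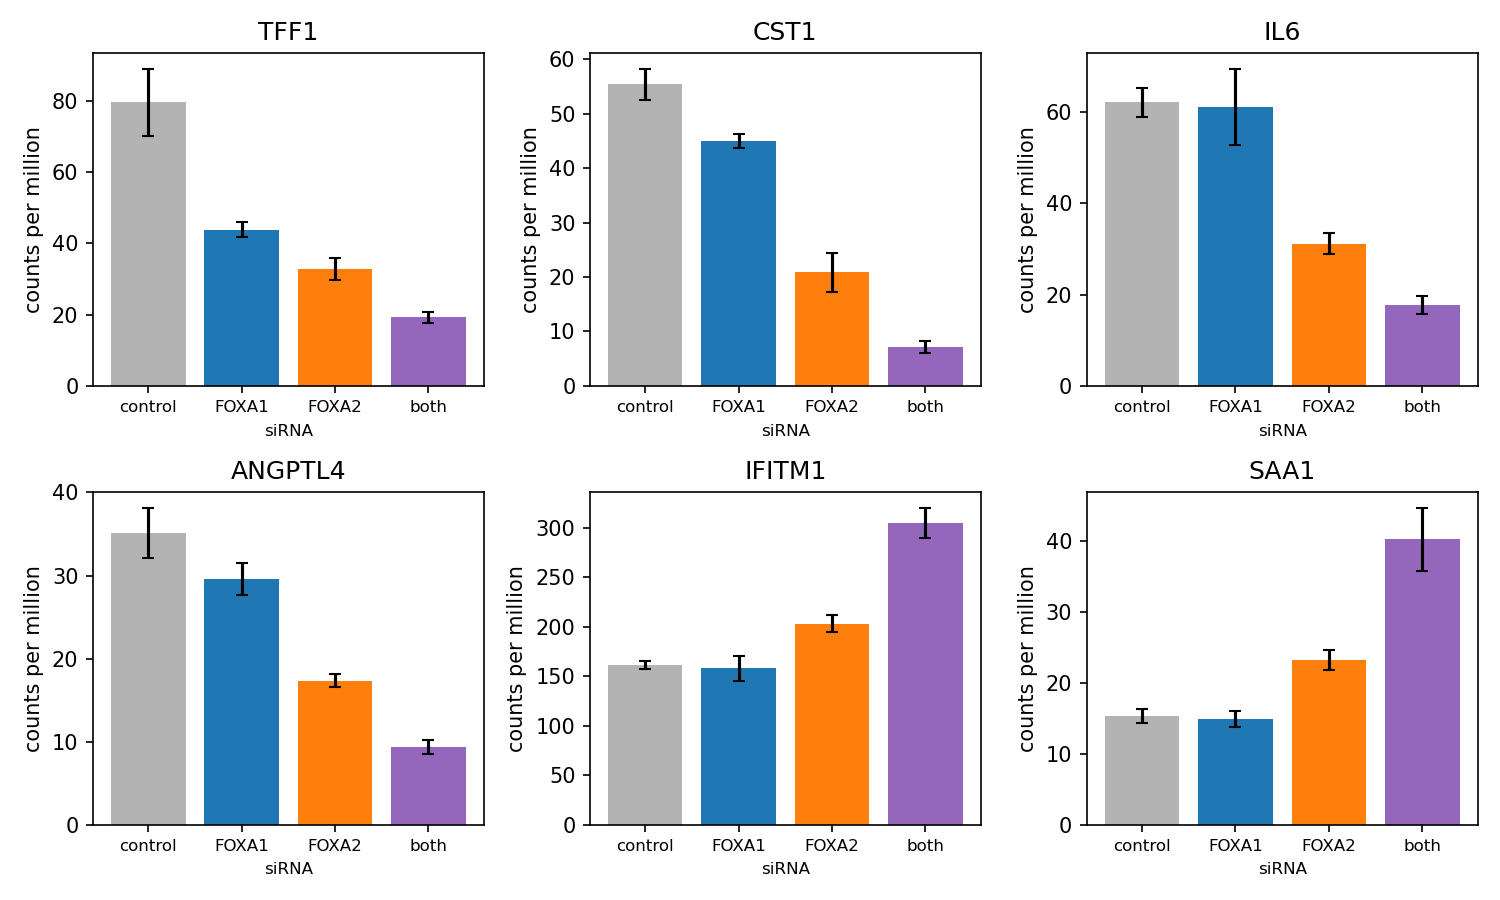
Mean abundance (CPM, vertical axis; bars, error bars SD, n = 3) of TFF1, CST1, IL6, ANGPTL4, IFITM1 and SAA1 in the 4 CFPAC1 groups. TFF1 falls from 79.6 with control siRNA to 19.2 CPM with both siRNAs, and IFITM1 rises from 161.2 to 305.2 CPM.

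The CFPAC1 libraries labelled with both siRNAs had the most calls of the comparisons with control siRNA. CST1 fell to 7.13 ± 1.09 CPM (SD, n = 3; log2 -2.96, SE 0.11; adjusted p = 3.37e-16), TFF1 to 19.2 ± 1.52 CPM (log2 -2.05, SE 0.09) and SERPIND1 by 2.98 on the log2 scale (SE 0.29). CLDN1 fell by 1.69 (SE 0.08), the vascular adhesion gene VCAM1 by 2.28 (SE 0.23) and CSF2, which encodes a myeloid growth factor, by 2.18 (SE 0.14). SPP1, which encodes the secreted phosphoprotein osteopontin, rose from 97.9 ± 17.6 to 394.4 ± 24.8 CPM (n = 3; log2 2.01, SE 0.12). The squamous keratin gene KRT13 rose by 1.89 (SE 0.16) and LEMD1 by 1.95 (SE 0.20). GAK also rose (log2 1.89, SE 0.46), but in unstranded libraries its reads cannot be told from those of overlapping genes. In total 2359 genes rose and 2383 fell of 13539 tested, with a median absolute log2 change of 0.440. At least a 2-fold change was measured for 442 of the genes that rose and 168 of those that fell.

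Interferon response genes were higher with both siRNAs, with 32 called higher and 4 lower of 46 (33 and 6 adjusted over the list alone; camera adjusted p = 7.9e-08, or 0.0695 with an estimated correlation). IFITM1, an antiviral membrane protein gene, rose from 161.2 ± 3.97 to 305.2 ± 15.4 CPM (n = 3), and PARP9 rose by 0.51 (SE 0.06) and BST2 by 0.47 (SE 0.05) on the log2 scale. Inflammatory genes were lower, with 17 called lower and 3 higher of 25 (18 and 3 adjusted over the list alone; adjusted p = 3.65e-12, or 0.0695 with an estimated correlation), and IL6 fell to 17.7 ± 2.01 CPM. The hypoxia and glycolysis list was lower with 17 of 26 called lower and 0 higher (19 lower adjusted over the list alone; adjusted p = 1.65e-12, or 0.0695 with an estimated correlation). ANGPTL4 fell from 35.1 ± 3.04 to 9.37 ± 0.866 CPM, and the glycolytic gene ENO2 by 1.03 on the log2 scale (SE 0.07). Acute phase genes were higher with 8 of 14 called, also adjusted over the list alone (adjusted p = 4.21e-05, or 0.0796 with an estimated correlation). SAA1, whose reads may be shared with SAA2, rose from 15.4 ± 0.989 to 40.2 ± 4.47 CPM, and the complement gene C3 rose by 0.51 (SE 0.06). Mucins were higher with 7 of 9 called (8 adjusted over the list alone; adjusted p = 0.000804, or 0.16 with an estimated correlation), including MUC1 (log2 0.99, SE 0.11) and MUC16 (log2 1.62, SE 0.28). YAP/TEAD targets were lower with 7 called lower and 1 higher of 22, also adjusted over the list alone (adjusted p = 8.59e-05, or 0.134 with an estimated correlation), and AJUBA fell by 1.14 (SE 0.08) and ANKRD1 by 0.93 (SE 0.05).

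Mesenchymal and EMT genes were lower with both siRNAs, with 10 called lower and 3 higher of 29 (11 and 4 adjusted over the list alone; adjusted p = 0.00347, or 0.134 with an estimated correlation); LOXL2 fell by 1.19 (SE 0.08) and the repressor gene SNAI2 by 0.92 (SE 0.08). The classical list was lower with 7 called lower and 3 higher of 15 (8 and 3 adjusted over the list alone; adjusted p = 0.000757, or 0.134 with an estimated correlation), a call lost with the GC offset (0.13). The cell cycle list was higher with 16 called higher and 3 lower of 38 (16 and 4 adjusted over the list alone; adjusted p = 0.00557, or 0.285 with an estimated correlation). The basal-like list was lower with 11 called lower and 4 higher of 23 (11 and 5 adjusted over the list alone; adjusted p = 0.0357, or 0.13 with an estimated correlation), except without control library 2 (0.0599), without double-knockdown library 3 (0.0519) and with the GC offset (0.0967). WNT targets were called lower (4 tested, adjusted p = 0.0456, or 0.16 with an estimated correlation), with a mean of -0.09 and a median of 0.15. The WNT call ended without control library 3 (0.0521), double-knockdown library 2 (0.0822) or 3 (0.0669) and with the GC offset (0.679). The DKK1 gene, a WNT antagonist of that list, fell by 1.05 on the log2 scale (SE 0.05).

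Other lists were not called with both siRNAs although single members changed. Epithelial identity had 13 called higher and 9 lower of 42 (adjusted p = 0.428), and ELF3 rose by 0.53 (SE 0.06) and ITGB4 by 0.62 (SE 0.06). The median of the epithelial list was 0.04 while the test pointed down. Foregut and pancreas transcription factors had 8 called higher and 4 lower of 24 (adjusted p = 0.21), with HHEX at 1.03 (SE 0.15) and NR5A2 at -1.05 (SE 0.19). Cholesterol biosynthesis had 12 higher and 4 lower of 22 (adjusted p = 0.121), the stress response 6 higher and 8 lower of 25 (0.4, median 0.06, mean -0.03), RAS/MAPK output 2 higher and 6 lower of 20 (0.132), p53 targets 3 higher and 2 lower of 18 (0.4, median 0.01 with the test down) and liver secretory genes 3 higher and 2 lower of 17 (0.747). CDKN1A, a p53 target that stops the cell cycle, fell by 1.16 (SE 0.06). Adjusted over the list alone, these counts were 13 and 10, 8 and 4, 12 and 4, 6 and 9, 2 and 6, 3 and 2, and 3 and 2. Acinar (4 tested, adjusted p = 0.428), endocrine (3, 0.21), leukocyte (4, 0.924) and neural genes (5, 0.446) were not called, and SCG2 and CHGB, secretory granule genes of the endocrine list, rose by 2.00 (SE 0.36) and 1.46 (SE 0.37). Mitochondrially encoded genes were not called (0 of 13 by edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2; adjusted p = 0.653). The fibroblast list could not be tested in CFPAC1, and the endothelial list had too few detected members in each line.

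**Figure D3:**
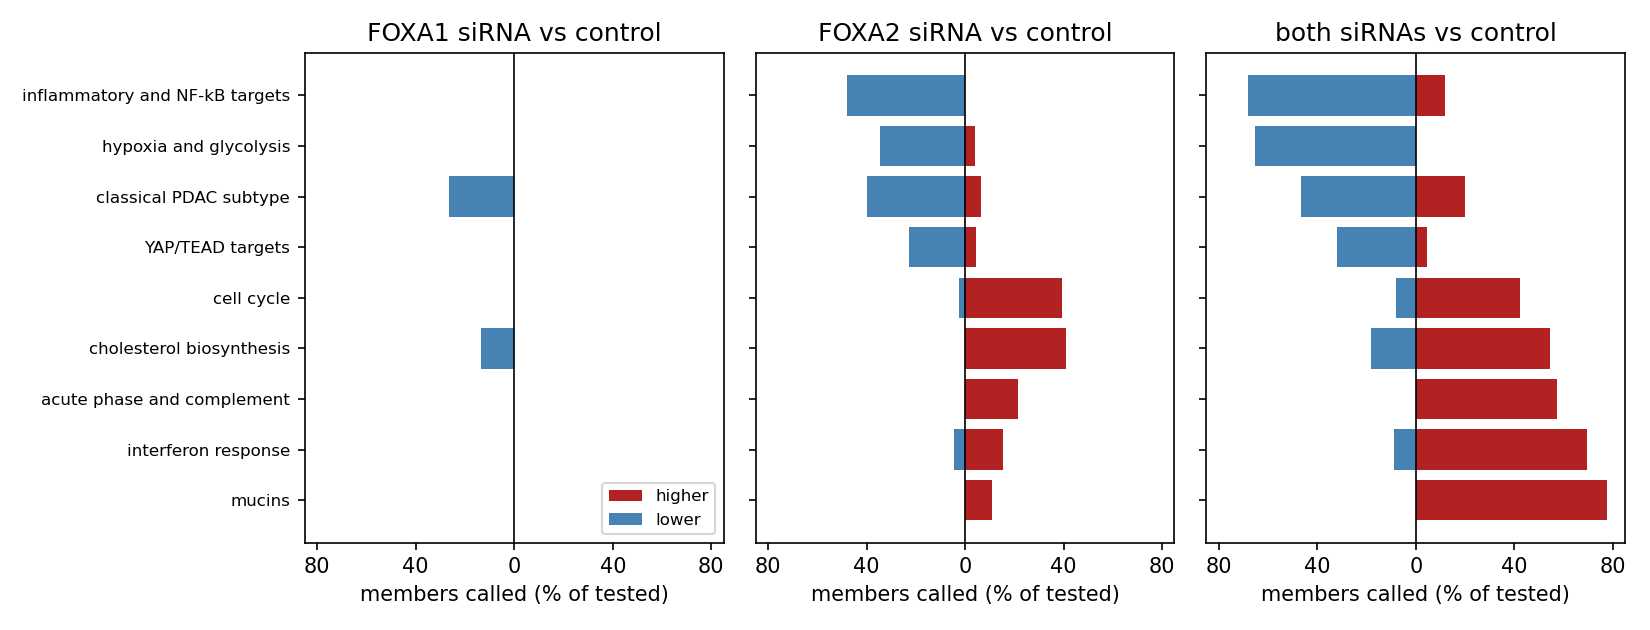
Percent of tested members (horizontal axis) called higher (red) and lower (blue) than control siRNA in 9 gene lists for FOXA1 siRNA, FOXA2 siRNA and both in CFPAC1. With both siRNAs 32 of 46 interferon genes were higher and 17 of 26 hypoxia genes were lower.

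The change with both siRNAs was related to the GC content of the transcript. The median log2 change ran from -0.04 over 2251 genes of at most 40% GC to 0.45 over 343 genes above 65% GC, where 130 genes rose and 8 fell. Across genes, which are not independent replicates, Spearman's correlation of the change with GC was 0.197, and 0.130 among the most highly expressed genes. With FOXA1 siRNA it was 0.174 and with FOXA2 siRNA 0.060. PPP1R16A (log2 2.07, SE 0.27) and ZNF580 (log2 1.91, SE 0.28) were among the largest rises with both siRNAs.

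**Figure D4:**
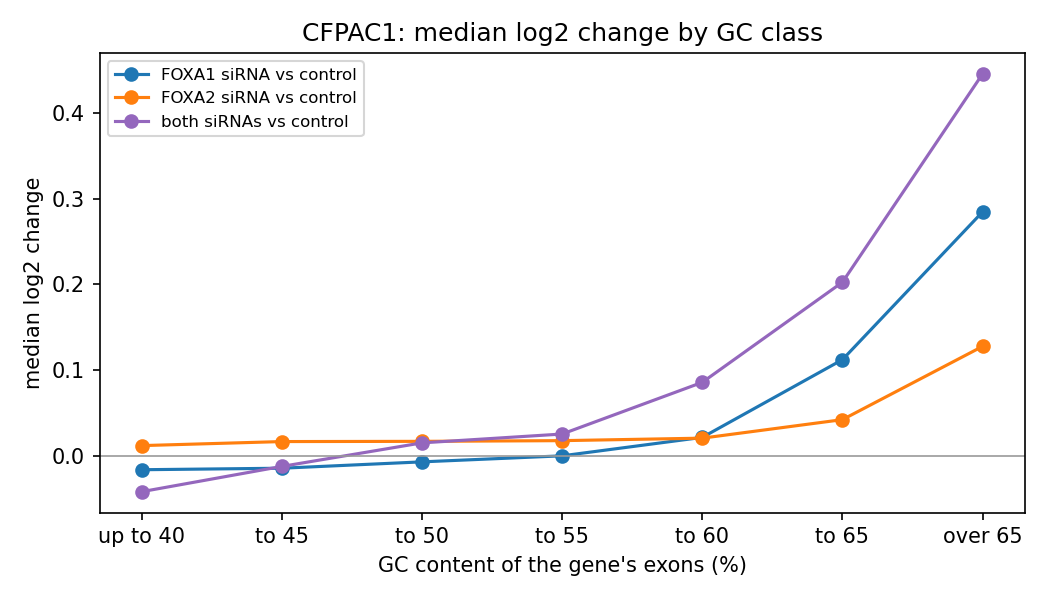
Median log2 change against control siRNA (vertical axis) in classes of transcript GC content (percent, horizontal axis) for the 3 CFPAC1 knockdowns. With both siRNAs the median runs from -0.04 to 0.45.

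FOXA1 and FOXA2 siRNA were compared directly in CFPAC1. CST1 was higher with FOXA1 than with FOXA2 siRNA by 1.11 on the log2 scale (SE 0.10, n = 3), as were the carboxypeptidase gene CPA4 by 1.04 (SE 0.08) and CLDN1 by 0.91 (SE 0.08). DHRS2 was lower by -1.69 (SE 0.19), TSC22D3, a glucocorticoid-induced gene, by -0.92 (SE 0.07) and TGFBR3 by -1.03 (SE 0.18). The cholesterol list was lower with FOXA1 siRNA, with 13 of 22 called lower and 0 higher, also adjusted over the list alone (camera adjusted p = 7.46e-14, or 0.0663 with an estimated correlation), led by IDI1 (log2 -0.45, SE 0.06) and HMGCS1 (log2 -0.43, SE 0.06). The basal-like list was higher, with 6 called higher and 3 lower of 23 (9 and 4 adjusted over the list alone; adjusted p = 0.000161), and held with an estimated correlation (0.047). Inflammatory genes were higher with 8 of 25 called (10 adjusted over the list alone; adjusted p = 8.37e-10, or 0.0753 with an estimated correlation), IL6 by 0.97 (SE 0.09). Cell cycle genes were lower with 12 called lower and 1 higher of 38 (17 and 1 adjusted over the list alone; adjusted p = 3.85e-07, or 0.0989 with an estimated correlation), with TOP2A at -0.43 (SE 0.05). The mitochondrially encoded list was also called lower (adjusted p = 0.0331, or 0.567 with an estimated correlation), except without FOXA1 siRNA library 2 (0.147), FOXA2 siRNA library 2 (0.813) or 3 (0.0995) and with the GC offset (0.14). In total 484 genes were higher and 502 lower with FOXA1 siRNA, and the 986 calls became 606 without FOXA2 siRNA library 2.

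FOXA1 siRNA given with FOXA2 siRNA was compared to each siRNA alone. Compared to FOXA1 siRNA alone, CST1 was lower with both by -2.66 on the log2 scale (SE 0.11, n = 3) and IL6 by -1.79 (SE 0.10), and LEMD1 was higher by 2.16 (SE 0.20). Compared to FOXA2 siRNA alone, CST1 was lower by -1.54 (SE 0.12), the cytokine gene IL1A by -1.25 (SE 0.20) and the vesicle transport gene RAB3B by -1.22 (SE 0.16), and COQ2, of ubiquinone synthesis, was higher by 1.37 (SE 0.17). The interferon list was higher with both siRNAs than with FOXA1 siRNA (30 called higher and 3 lower of 46, 34 and 3 adjusted over the list alone; camera adjusted p = 1.28e-13), a call that held with an estimated correlation (0.025), and than with FOXA2 siRNA (19 of 46 higher, 22 higher and 1 lower adjusted over the list alone; adjusted p = 2.04e-10, or 0.0561 with an estimated correlation). The hypoxia list was lower than with FOXA1 siRNA (16 of 26 lower, 17 adjusted over the list alone; adjusted p = 5.06e-14, or 0.0369 with an estimated correlation) and than with FOXA2 siRNA (14 lower, 17 adjusted over the list alone; adjusted p = 9.43e-12, or 0.0751 with an estimated correlation), and BNIP3, a mitophagy gene, was lower by -0.73 (SE 0.05) and -0.52 (SE 0.05). SAA1 of the acute phase list was higher by 1.43 (SE 0.10) and 0.79 (SE 0.10), with 9 and 5 of 14 members called (9 and 7 adjusted over the list alone; adjusted p = 2.55e-09 and 4.73e-07, or 0.0318 and 0.065 with an estimated correlation). FOXA3 was higher with both than with FOXA1 siRNA (log2 1.43, SE 0.42; adjusted p = 0.0128), but not without FOXA1 siRNA library 1 (0.0794). Against FOXA1 siRNA 1541 genes were higher and 1825 lower, and against FOXA2 siRNA 785 and 854. The 1639 calls against FOXA2 siRNA became 822 without FOXA2 siRNA library 2 and 901 without double-knockdown library 1.

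Calls of the CFPAC1 comparisons overlapped. TFF1 fell with each siRNA, and 37 genes fell and 15 rose with both FOXA1 siRNA and FOXA2 siRNA, where 3.35 and 0.928 were expected from their numbers. FOXA2 siRNA and the double knockdown shared 686 falls and 462 rises, CST1 and DHRS2 among them, with 0 genes in opposite directions (expected 128.7 and 95.1; edgeR). These expected counts do not allow for the control libraries that enter both changes. In simulations with shared controls and no effect of any siRNA the correlation across genes was 0.504, compared to 0.719 for FOXA2 siRNA and both. For FOXA1 and FOXA2 siRNA it was 0.465 compared to 0.497 in simulations, and for FOXA1 siRNA and both 0.497 compared to 0.505. These correlations were not above those of shared controls. Changes particular to a single siRNA lower a correlation but not a covariance, so the correlation alone does not decide. The covariance across genes was above that in the simulations. It was 0.0405 compared to 0.0209 in simulations for FOXA1 and FOXA2 siRNA and 0.067 compared to 0.021 for FOXA1 siRNA and both. The simulations held no trend of the change with GC or expression, which the real changes had. Such a trend in the shared control libraries would raise covariances and correlations too. The covariance therefore does not decide whether the siRNAs shared an effect. No simulation gave a shared call, but simulations without any effect could hardly give one, so that count decides nothing. From separate libraries, the FOXA2 siRNA change against control and the double knockdown change against FOXA1 siRNA correlated at 0.517 across genes (0.00517 in simulations), and 96.2% of the 1277 genes had the same sign. The FOXA1 siRNA change against control and the double knockdown change against FOXA2 siRNA correlated at 0.281, and 87.1% of the 85 genes had the same sign. These 2 changes had like trends with GC (Spearman 0.174 and 0.231) and mean log2 CPM (-0.170 and -0.164), which can add to their correlation. For the FOXA2 siRNA pair the values were 0.060 and 0.124 with GC and -0.215 and -0.175 with mean log2 CPM. Between the PANC1 change with the FOXA2-deleted label and the CFPAC1 change with FOXA2 siRNA the correlation was 0.103, with RBP4 lower in both.

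The double knockdown was tested against the sum of both single knockdowns in CFPAC1. SAA1 was higher than that sum by 0.83 on the log2 scale (SE 0.14, n = 3), IFITM1 by 0.62 (SE 0.08) and CP, which encodes ceruloplasmin, by 0.89 (SE 0.16). CST1 was lower than the sum by -1.25 (SE 0.15), IL6 by -0.79 (SE 0.13) and the coagulation initiator gene F3 by -0.51 (SE 0.07). The interferon (6 of 46 higher, 22 adjusted over the list alone; camera adjusted p = 6.57e-16) and acute phase lists (3 of 14 higher, 7 adjusted over the list alone; adjusted p = 1.72e-11) were above the sum and held with an estimated correlation (0.0138 and 0.0154). The hypoxia list (3 of 26 lower, 10 adjusted over the list alone; adjusted p = 8.49e-10, or 0.0792 with an estimated correlation) and YAP/TEAD targets (3 of 22 lower, 7 adjusted over the list alone; adjusted p = 5.08e-07, or 0.0792 with an estimated correlation) were below it, with BNIP3 at -0.54 (SE 0.06) and ANKRD1 at -0.51 (SE 0.07). In total 92 genes were above and 74 below the sum. The 166 calls became 91 without control library 2, 110 without FOXA1 siRNA library 1 and 102 without double-knockdown library 3.

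The change between FOXA2-deleted and wild-type labels in PANC1 was compared to the change between FOXA2 and control siRNA labels in CFPAC1. LAMB3, a laminin gene of epithelial basement membranes, went from 0.591 to 7.68 CPM in PANC1 and from 886.7 to 668.1 CPM in CFPAC1 (difference of log2 changes 4.08, SE 0.59, n = 3). G0S2, an inhibitor of lipolysis, went from 1.47 to 28.4 CPM in PANC1 and from 145.9 to 131.5 CPM in CFPAC1 (difference 4.38, SE 0.74). DEPTOR, an mTOR inhibitor gene, had a difference of -3.07 (SE 0.47) and the protease inhibitor gene SPINT1 one of -3.03 (SE 0.49). The inflammatory list had a median difference of 1.32 with 22 of 26 positive (camera adjusted p = 4.45e-12, or 0.212 with an estimated correlation). edgeR called 0 of its members, 15 had an unadjusted p under 0.05, 14 were higher adjusted over the list alone, and DESeq2 called 3. The mitochondrially encoded list, which reads on RNA quality, was called lower in the same comparison (adjusted p = 0.0028, or 0.567 with an estimated correlation), except without PANC1 wild-type library 1 (0.164), FOXA2-deleted library 3 (0.0829) or both (0.793). Of 14119 genes 24 were above and 41 below 0. The 65 calls became 141, 151, 104 and 24 without PANC1 wild-type library 1 or 3 or FOXA2-deleted library 1 or 2. Without CFPAC1 control library 1, 2 or 3 or FOXA2 siRNA library 1 or 2 they became 3, and without FOXA2 siRNA library 3 they became 5. Without each of these CFPAC1 libraries the adjusted p was 0.0546 to 0.0711 for LAMB3, 0.0761 to 0.112 for G0S2 and 0.0579 to 0.0746 for both DEPTOR and SPINT1. The G0S2 call also ended without PANC1 wild-type library 1 (0.0539) and the SPINT1 call without FOXA2-deleted library 2 (0.0538).

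The wild-type PANC1 and control CFPAC1 libraries differed in epithelial genes. EHF, an epithelial ETS factor gene, had 97.9 ± 4.24 CPM in CFPAC1 and 0.317 ± 0.207 CPM in PANC1 (SD, n = 3), and CDH1, which encodes E-cadherin, was lower in PANC1 by -5.02 on the log2 scale (SE 0.43). The mesenchymal filament gene VIM was higher in PANC1 by 1.37 (SE 0.20). FOXA1 was lower in PANC1 by -4.51 (SE 0.48; adjusted p = 1.59e-05), and FOXA2 was higher by 1.64 (SE 0.39; adjusted p = 0.00269). Among lists, 34 of 42 epithelial genes were lower in PANC1 and 2 higher (35 and 2 adjusted over the list alone; camera adjusted p = 2.31e-14), and 22 of 23 basal-like genes were lower, also adjusted over the list alone (adjusted p = 3.27e-24). Both calls held with an estimated correlation (0.0148 and 0.000413), as did the classical, foregut, liver, acute phase and hypoxia lists. The fibroblast list was higher in PANC1 (adjusted p = 0.0402, or 0.17 with an estimated correlation), except without PANC1 wild-type library 2 (0.0924), without CFPAC1 control library 1 (0.106), 2 (0.0941) or 3 (0.0701), without both PANC1 wild-type library 1 and FOXA2-deleted library 3 (0.0632), with the replicate block (0.0524) and with the GC offset (0.174). In total 4658 genes were higher and 4610 lower in PANC1 of 14119 tested. Line, medium and transfection differ together, so this comparison is not of the lines alone.

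In the authors' deposited table for PANC1, 89 genes were higher and 184 lower at a false discovery rate under 0.05, and FOXA2 was higher (log2 1.76, false discovery rate 3.32e-05). All 8 genes called here, CLU and RBP4 among them, were in that table in the same direction, and the log2 changes of both analyses differed by a median of 0.01. The authors' deposited table for both siRNAs held 2752 higher and 2233 lower genes, of which 4461 were also called here, and gave FOXA2 a log2 change of 1.09. In the authors' deposited table for FOXA1 siRNA, 70 genes were higher and 92 lower, and in that for FOXA2 siRNA 625 and 705, with 84 and 1149 also called here.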

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

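Tests of the difference between changes were set before the data were examined, while the GC offset was chosen after the result was seen. In CFPAC1 the libraries with both siRNAs departed from the sum of the FOXA1 and FOXA2 siRNA changes for some genes. A test of that difference called 166 of 13539 genes and 12 gene lists. With an estimated correlation 3 of the 12 lists stayed called, and with the fold minimum 0 genes were called by edgeR (150 at an unadjusted p under 0.05), compared to 254 by DESeq2 without it. Among genes of interferon response and acute phase, the double knockdown lay above the sum for IFITM1 (log2 0.617), SAA1 (0.833), CP (0.888) and C3 (0.424). It also lay above the sum for the sodium-dependent phosphate carrier gene SLC34A2 (1.204), the tetraspanin gene TSPAN8 (0.737), ELF3 (0.546) and AGR2 (0.356). It lay below the sum for CST1 (-1.245), IL6 (-0.793), SFRP1 (-1.164), GFPT2 (-1.290), COL4A2 (-0.839), LOXL2 (-0.643), BNIP3 (-0.539), ANKRD1 (-0.512), F3 (-0.508) and DKK1 (-0.423). These 18 calls held without each library in turn.

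Other genes of that test depended on single libraries. LEMD1 (1.418) was not called without control library 3 (adjusted p = 0.0518), and MMP9 (-1.476) not without control library 2 (0.0509) or FOXA1 siRNA library 1 (0.0512). IGFBP7 (1.023) was not called without control library 3 (0.0825) or double-knockdown library 1 (0.0622), and PTRF (-1.035) not without control library 2 (0.0706) or double-knockdown library 3 (0.0694). ANGPTL4 (-0.638) was lost without control library 2 (0.0804), FOXA1 siRNA library 1 (0.0569) or double-knockdown library 3 (0.0747). BIRC3 (-0.443) was lost without control library 2 (0.0817) or double-knockdown library 2 (0.0515) or 3 (0.0616). PARP9 (0.343) was lost without control library 2 (0.0654) or double-knockdown library 1 (0.0597) or 2 (0.0579). IFI6 (0.373) was lost without control library 2 (0.0603), FOXA1 siRNA library 1 (0.0727) or double-knockdown library 1 (0.0717) or 3 (0.0592). SECTM1 (1.112) was lost without control library 2 (0.0603) or 3 (0.0978), FOXA1 siRNA library 1 (0.0727), FOXA2 siRNA library 2 (0.0617) or double-knockdown library 1 (0.0831) or 3 (0.0828). PDK4 (1.148) was lost without control library 1 (0.0625), 2 (0.063) or 3 (0.0884), FOXA1 siRNA library 1 (0.131), FOXA2 siRNA library 1 (0.103) or double-knockdown library 1 (0.0619), 2 (0.0566) or 3 (0.114). The count of 166 genes became 91 without control library 2, 110 without FOXA1 siRNA library 1 and 102 without double-knockdown library 3. Of 100 splits of the libraries, 1, the real one with its 166 genes, gave as many calls, and the highest of the others gave 14. The other splits mixed libraries of all groups, so the changes with each siRNA entered the spread and could lower those counts. The splits therefore do not decide whether chance gave the 166 calls. The splits say nothing on differences between transfections, which the labels do not give.

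The change with the FOXA2-deleted label in PANC1 and that with the FOXA2 siRNA label in CFPAC1 differed for 65 genes and 12 gene lists by a test of the difference. With an estimated correlation 0 of the 12 lists stayed called. The difference was positive for LAMB3 (log2 4.075), G0S2 (4.384), NAV3 (2.843), CPA4 (2.440), CD83 (2.142), ANGPTL4 (1.421), DDX58 (0.943) and SLC2A1 (0.867). It was negative for HOOK1 (-3.586), DEPTOR (-3.069), SPINT1 (-3.031), PLSCR4 (-2.720), CNNM1 (-2.695) and RBP4 (-2.337). These 14 calls ended without each of CFPAC1 control libraries 1, 2 and 3 and FOXA2 siRNA libraries 1, 2 and 3 (adjusted p between 0.0544 for RBP4 and 0.141 for SLC2A1), except that PLSCR4 stayed called without FOXA2 siRNA library 3. Without FOXA2-deleted library 2 the calls of NAV3 (0.0643), HOOK1 (0.084), DDX58 (0.0558), SPINT1 (0.0538) and SLC2A1 (0.107) ended too. HOOK1 (0.0554) and SLC2A1 (0.0529) were lost without FOXA2-deleted library 3, SLC2A1 without FOXA2-deleted library 1 (0.0641), and G0S2 without PANC1 wild-type library 1 (0.0539). The GC offset ended the calls of ANGPTL4 (0.0512) and SLC2A1 (0.0507). The 65 calls became 141, 151, 104 and 24 without PANC1 wild-type library 1 or 3 or FOXA2-deleted library 1 or 2. They became 3 without CFPAC1 control library 1, 2 or 3 or FOXA2 siRNA library 1 or 2, and 5 without FOXA2 siRNA library 3. Of 100 splits, 1, the real one with its 65 genes, gave as many calls, and the highest of the others gave 40. The other splits mixed the groups within each line, so changes between the groups entered the spread and could lower those counts. Neither chance in how the libraries were assigned nor a difference between cultures or transfections can be excluded by that count. PANC1 had a deletion and CFPAC1 an siRNA, by their labels, so the line and the method differ together. An exchange of the PANC1 labels, which was not excluded, would turn the PANC1 change and so alter the sign or size of these differences.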

How the results depend on the processing

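The GC offset, the likelihood-ratio test, both limma tests and the setting that left out 2 PANC1 libraries were chosen after the result was seen. The causes of the changes below were not tested unless a setting's own construction gives them.

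The 8 calls of FOXA2-deleted against wild-type PANC1 became 5 with DESeq2 size factors, 21 without the filter on low counts, 288 with DESeq2, 248 with the likelihood-ratio test, 123 with limma quality weights, 3 with limma without weights, 24 without wild-type library 1 and FOXA2-deleted library 3, and 909 in a single fit with CFPAC1, which shares one dispersion between both lines. edgeR called 0 with the replicate block (890 genes at an unadjusted p under 0.05), 0 with the fold minimum (419) and 0 with the GC offset and block (931). Leaving out single libraries gave 0 to 1 calls, 0 without wild-type library 2 or 3 or any FOXA2-deleted library (656 to 1296 at an unadjusted p under 0.05).

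The 85 calls with FOXA1 siRNA became 422 without the filter, 208 with DESeq2, 161 with the GC offset, 202 with the offset and block, 176 with the likelihood-ratio test, 143 with quality weights and 129 with only the 2 groups compared, and ranged from 35 to 90 in leave-one-out. The fold minimum of 1.5, which removes small changes by construction, left 0 calls with FOXA1 siRNA (88 at an unadjusted p under 0.05), 17 with FOXA2 siRNA, 339 with both, 8 between the single siRNAs, 180 and 10 for both against FOXA1 and FOXA2 siRNA, 0 for non-additivity (150 at an unadjusted p under 0.05) and 5 between the lines. The 166 calls of non-additivity became 321 without the filter and 254 with DESeq2. The 65 calls between the lines became 19 with the block, 18 with the GC offset and block, 286 with DESeq2, 272 with the likelihood-ratio test, 260 with quality weights and 352 without both PANC1 libraries.

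Leave-one-out counts ranged from 866 to 1224 with FOXA2 siRNA, 3792 to 4238 with both, 606 to 1130 between the single siRNAs, 2682 to 3002 and 822 to 1849 for both against each, 91 to 201 for non-additivity, 3 to 151 between the lines and 8528 to 9498 between the controls. Called lists ranged from 7 to 12 in PANC1, 2 to 4, 9 to 15 and 9 to 11 with FOXA1, FOXA2 and both siRNAs, 9 to 13, 11 to 12 and 7 to 9 among knockdowns, 10 to 13 for non-additivity, 7 to 13 between the lines and 12 to 15 between the controls. The estimated correlation left 0 of 10 called lists in PANC1, 0 of 2, 0 of 13 and 0 of 11 with FOXA1, FOXA2 and both siRNAs, 1 of 12, 4 of 12 and 0 of 8 among knockdowns, 3 of 12 for non-additivity, 0 of 12 between the lines and 7 of 13 between the controls. Without both PANC1 libraries 4 lists were called in PANC1 and 5 between the lines. At an adjusted p under 0.01, shared calls fell from 52 to 22 (FOXA1 and FOXA2 siRNA), 73 to 27 (FOXA1 siRNA and both), 1148 to 583 (FOXA2 siRNA and both), 973 to 518 and 43 to 14 (separate libraries), and 1 and 2 to 0 and 0 (PANC1 against FOXA2 siRNA and both), since fewer genes pass.

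Direction reversed for the mitochondrially encoded list in PANC1 without both libraries (adjusted p = 0.536), its cell cycle list without wild-type library 1 (0.516, leave-one-out range 1.18e-08 to 0.516), and the cell cycle list between the lines without both libraries (0.251) or wild-type library 1 (0.00479, range 3.01e-05 to 0.229). LINC00261 reversed in PANC1 without wild-type library 2 (log2 0.091, range -0.448 to 0.091), with FOXA1 siRNA without control library 2 (-0.274) or 3 (-0.017) or FOXA1 siRNA library 2 (-0.191, range -0.274 to 0.419), with FOXA2 siRNA without control library 2 (-0.116) or FOXA2 siRNA library 2 (-0.219, range to 0.585), and with both without control library 2 (-0.021, range to 0.668). With FOXA1 siRNA, FOXA2 reversed without control library 3 (-0.21) or FOXA1 siRNA library 3 (-0.08, range -0.21 to 0.607) and FOXA1 without control library 1 (0.259) or FOXA1 siRNA library 1 (0.076, range -0.518 to 0.259).

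Among named genes, all 32 called between the controls stayed called under every alternative, as did 46 of 83 with both siRNAs and 14 of 61 with FOXA2 siRNA, or 77 and 56 when the fold minimum is set aside. In PANC1 0 of 6 and 9 of 33 with FOXA1 siRNA stayed called in all but the fold minimum. Over alternatives, gene values kept direction and side 5260 times and became weaker 602 times, 207 of them under the fold minimum, and list tests kept theirs 907 times and became weaker 213 times, 90 of them with the estimated correlation. FOXA1 and FOXA2 had fewer than 100 counts in each CFPAC1 library, and their intervals cover counting error and the spread between libraries together.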

Other observations

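The limma test without weights, the bounds of the FOXA1 and FOXA2 folds, the search for overlapping genes, the comparison of library totals, the test without both PANC1 libraries and all tests with the GC offset were chosen after the result was seen.

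With both siRNAs in CFPAC1, the trefoil factor gene TFF1 and the cytokine gene IL6 fell while IFITM1 and SAA1 rose. A response to FOXA2 siRNA that is shared with the double knockdown may account for part of these changes, since changes from separate libraries had a correlation across genes of 0.517. A FOXA2 siRNA response of equal size with and without FOXA1 siRNA does not account for all. IFITM1 (0.62), SAA1 (0.83) and IL6 (-0.79) lay beyond the sum of both single changes. A stronger response to FOXA2 siRNA in the double knockdown stays open and was not tested. Mucins went the other way from TFF1, with 7 of 9 called higher, but the call of their list ended with an estimated correlation. In the PANC1 libraries labelled FOXA2-deleted the interferon list was also higher, with 32 of 41 members positive, and the classical list was also lower, but edgeR called 0 members of either (10 and 3 at an unadjusted p under 0.05, 4 and 1 by DESeq2) and both calls ended with an estimated correlation (adjusted p = 0.347). The inflammatory list was higher in PANC1, with 0 members called (9 at an unadjusted p under 0.05, 2 by DESeq2), and lower in CFPAC1 with both siRNAs. With an estimated correlation it was called in neither (adjusted p = 0.347 and 0.0695).

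FOXA2 counts were not lower in the CFPAC1 libraries labelled with its siRNA, and FOXA1 counts were lower by less than the spread between libraries (folds of 0.915 with FOXA1 siRNA and 0.751 with both). A strong fall of FOXA2 mRNA is argued against by the lower bounds of its fold, 0.978 with FOXA2 siRNA and 1.236 with both. These bounds rest on normal quantiles and few counts, 7 to 21 with control siRNA and 23 to 38 with both. A small fall is therefore not excluded. The call of the rise with both siRNAs was lost with DESeq2, with the GC offset and without some single libraries. For FOXA1 the lower bound was 0.578 with FOXA1 siRNA alone, which argues against a much stronger fall but leaves a milder one open. A knockdown of FOXA1 stays open with both siRNAs, where the lower bound was 0.4695. Reads lost to other counted genes are argued against by 0 overlapping features among the 27123, and genes outside these were not searched. Random assignment of siRNA labels is argued against by the correlation of 0.5174 between FOXA2 siRNA changes from separate libraries. Labels exchanged between whole groups would give that value too and stay open. An effect of siRNA on protein without a fall of polyA RNA, and off-target effects, may both remain and were not tested.

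Few genes were called between FOXA2-deleted and wild-type PANC1, although RBP4, a retinol carrier gene, and CLU, a chaperone gene, fell by 2.93 and 1.80 on the log2 scale. The PANC1 libraries did differ with GC content. Relative to each gene's mean, genes above 65% GC had a median log2 CPM of -0.365 in wild-type library 1. The median was -0.148 in FOXA2-deleted library 3 and 0.069 to 0.199 in the other PANC1 libraries. That trend as the cause of the few calls is argued against by 9 calls with the offset compared to 8. Wild-type library 1 standing apart stays open: leaving it out gave 1 call, but leaving out any other library gave 0 in edgeR (656 to 1296 genes at an unadjusted p under 0.05), so the test could not show an effect of that library, and 24 genes were called without it and FOXA2-deleted library 3. Uneven library quality may be part of the cause, since limma called 123 genes with quality weights and 3 without, and wild-type library 1 had a weight of 0.317. An exchange of the PANC1 labels and differences between bulk lines other than FOXA2 stay open and were not tested.

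The rise of genes rich in GC with both siRNAs, such as PPP1R16A, may be partly technical. GC content as the whole cause of the calls is argued against by 4790 calls with the offset compared to 4742, of which 4233 were shared. For genes above 65% GC the offset centres the class, from a median of 0.45 to 0.12, so the 42.31% that stayed called does not decide and technical and biological causes cannot be told apart for them. Low expression as the sole cause of the GC trend is argued against by a correlation of 0.1303 among the most highly expressed genes. Depth is argued against by 1 double-knockdown library outside the range of control totals. The change with both siRNAs also ran with expression (Spearman -0.2625 with mean log2 CPM across genes). Its median was 0.196 over the 4512 genes of lowest expression (683 called higher, 226 lower). Over the 4512 genes of highest expression the median was -0.0735 (685 called higher, 1584 lower). Whether low expression shaped some of the calls was not tested and stays open.

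For the other comparisons the 10 splits of the libraries are too few for a share under 0.05, and in each 1 of 10, the real split, gave as many calls. The real count and the highest other were 8 and 0 in PANC1, where CLU and RBP4 were called, 85 and 0 with FOXA1 siRNA, 1277 and 22 with FOXA2 siRNA, 4742 and 0 with both, 986 and 50 between the single siRNAs, 3366 and 0 for both against FOXA1 siRNA, 1639 and 0 for both against FOXA2 siRNA, and 9268 and 0 between the controls.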
